A study of Mus musculus with 25 samples.

How the data were processed

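Total RNA of single tibialis anterior muscles was hybridised to Affymetrix Murine Genome U74 version 2 arrays, array A of the set, 1 array per sample, 25 in all. Per the labels' protocols, muscle was homogenised in TRIzol and RNA purified on RNeasy columns. The deposited values are intensity signals on a linear scale, 1 per probe set, which the authors computed with MAS5 per the submitters' processing notes. The version of MAS5, the detection calls and the scan settings are not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal. The mean of each array's signals after trimming 2% at either end lay between 149.95 and 149.96, so the values were taken as scaled by the authors to a common level. Such scaling makes changes relative to the bulk of the array. No array pair was identical at over 50% of probe sets, and the highest correlation between a pair of arrays was 0.972.

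Probe sets were named through a table of the platform's annotation, with symbols brought up to date through gene identifiers in a RefSeq gene table of the mouse. Of 12488 probe sets, 66 were Affymetrix controls. Of the other 12422, 10855 had 1 gene symbol, 396 had several and 1237 were not in the table and are unnamed here. Only probe sets with 1 symbol were named. They covered 8252 genes, and 16 of them had a gene identifier absent from the RefSeq table and kept their symbol. No genomic position is given, because no genome build is named for the array. A gene was represented by its probe set with the highest mean log2 value over all 25 arrays. Among the named genes, several probe sets and at least 1 call were present in 259 gene and comparison pairs, of which 3 had calls in both directions. In others only part of the probe sets were called, such as 1 of 2 for Mbp and 2 of 6 for Ighm after freeze at 1 day.

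Signals were taken to log2 after adding 13 units, the 20th percentile of all values. Probe sets above the 40th percentile of their array on at least 2 arrays were tested, without Affymetrix controls, which left 9506 probe sets for 6919 genes. One linear model with a mean for each of the 9 groups was fitted to all 25 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance), with 16 residual and 5.46 prior degrees of freedom. The groups thus shared 1 estimate of the spread. Comparisons were each injury at each time against control, freeze minus contraction at each time, and the mean of that difference over the 4 times, 13 in all. Moderated F tests covered any change against control and the injury by time interaction. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. Depth has no counterpart on arrays, and the 2 or 3 arrays per group limit the precision.

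Apart from later additions, the 32 gene lists, rule for named genes, tests and alternative settings were fixed before the data were examined. The tests on a freeze array that lay among the controls and on the heat shock genes were chosen after those results had been seen. The test of clock genes was fixed after Dbp had been seen and before the other clock genes were looked at. Lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation, with adjustment over the lists within a comparison. With all 25 arrays 173 of 416 list results were called, of which 143 were lost with an estimated correlation. Where a called list result is printed with 1 p-value, the call was kept with an estimated correlation, but at a larger p. The lists covered stress, immune, matrix, muscle and metabolic genes and markers of fibroblasts, endothelium, nerve, fat, tendon, epithelium, blood and smooth muscle. The named genes of an injured group were the 5 with the largest rise and the 5 with the largest fall among those called, at least 2-fold changed and with every injured array beyond every control. For freeze minus contraction the 8 highest and 8 lowest were taken by the same rule, the mean over times needing 1 sign at all 4 times. The interaction gave the 10 genes with the smallest p. Of each list the 2 members with the largest rise and the 2 with the largest fall were named, with 37 representatives chosen in advance, some of which had no single-symbol probe set that passed the filter.

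The overlap of calls was set beside 100 simulations of unchanged groups that share the 3 controls. Alternatives were other pseudocounts, a floor, quantile normalization, centring on the median, other filters, only the groups compared in the fit, no trend, robust eBayes, array weights, adjacent sample numbers as a random block, 1 probe set per gene, stricter thresholds and leaving out each array. Leaving out sample 436 for list tests, overlaps and the naming rule was added after its position among the controls had been seen. Where leaving out an array left 1 in a group, the model assumed that it varied like the other groups. The procedure was tested on simulated data for the 9506 probe sets, with 200 of them changed. For contraction at 6 hours against control it recovered 39.4% of 2-fold and 84.8% of 4-fold changes with 4.61% false calls. For freeze minus contraction at 7 days the shares were 26.2%, 77.8% and 4.94%, and for the mean over times 88.8%, 99.8% and 4.46%. The interaction recovered 59% of 4-fold changes with 4.07% false calls. Data with no change gave 0 calls over the 13 comparisons and the interaction, by limma, and camera called 1 list, the 1 that had been shifted. Simulated probe sets varied independently, with the same spread in all groups and no outlying array. These rates therefore do not cover correlated genes or an array such as sample 436. They also do not test the preset correlation of camera. Figures were drawn with Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9.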

Results

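Gene expression was measured in the tibialis anterior, a fast muscle of the lower leg, of female C57BL/6J mice 2 to 3 months old. Muscles were injured either by 150 eccentric contractions in vivo, in which the active muscle is stretched, or by freezing with a steel probe 6 mm wide held at dry ice temperature for 10 s. They were taken at 6 hours, 1 day, 3 days or 7 days. Each group held 3 arrays, except contraction at 1 day and freeze at 7 days with 2 each, and 3 uninjured muscles served as controls, which gave 25 arrays in 9 groups. The comparisons ask what each injury changed over time and where the 2 injuries differed. Values are signals on arrays that the authors had scaled to a common trimmed mean, which lay between 149.95 and 149.96 on all 25. Their number, rather than a read depth, limits the precision. Changes are log2 values of signal plus 13 units ± SE, which understates changes of dim genes. The labels do not say whether any samples shared a mouse, so p-values measure the spread between these samples, part of which may be technical.

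Arrays of one group correlated at r = 0.921 to 0.972 across probe sets, with 1 exception. The array labelled freeze at 3 days, sample 436, correlated at 0.711 with each of the other 2 arrays of its group, samples 450 and 468, which correlated at 0.972 with each other. Its correlation with the controls was 0.935 to 0.942, against 0.921 to 0.948 between controls. Lgals3, which encodes galectin 3 and is high in macrophages, gave a signal of 11.8 on this array, 2779 and 2727 on the other 2 and 18.5 ± 12.1 (SD, n = 3) in controls. The array was kept in its labelled group. Counts of calls without it are given for each comparison, with those of the list results printed that then differed by over 1.5 times or in their call. Leaving it out lowered the median residual SD from 0.385 to 0.323 log2 units, raised the prior degrees of freedom from 5.46 to 7.43 and changed the fold changes of comparisons that involve freeze at 3 days. Calls were then more in all comparisons, and fold changes that do not involve this group stayed as they were. The 3'/5' signal ratio of the actin control probes, used as a sign of RNA integrity, also differed between groups. It was 0.560 to 0.595 in controls, 0.617 to 0.641 after contraction and 1.01 to 1.31 after freeze at 1 day, and 0.923 to 1.21 after contraction and 0.741 to 1.09 after freeze at 3 days. It was 0.572 to 0.669 after contraction and 0.657 to 0.955 after freeze at 6 hours, and 0.522 to 0.716 after contraction and 0.776 to 0.808 after freeze at 7 days. That of Gapdh ranged from 0.797 to 1.13 over the 25 arrays. It did not rise with the actin ratio. The Gapdh ratio was 0.869 to 1.13 in controls and 0.825 to 1.04 after freeze at 1 day. At 3 days it was 0.923 to 1.12 after contraction and 0.878 to 0.995 after freeze. The actin ratio alone therefore does not settle whether RNA integrity differed.

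**Figure D1:**
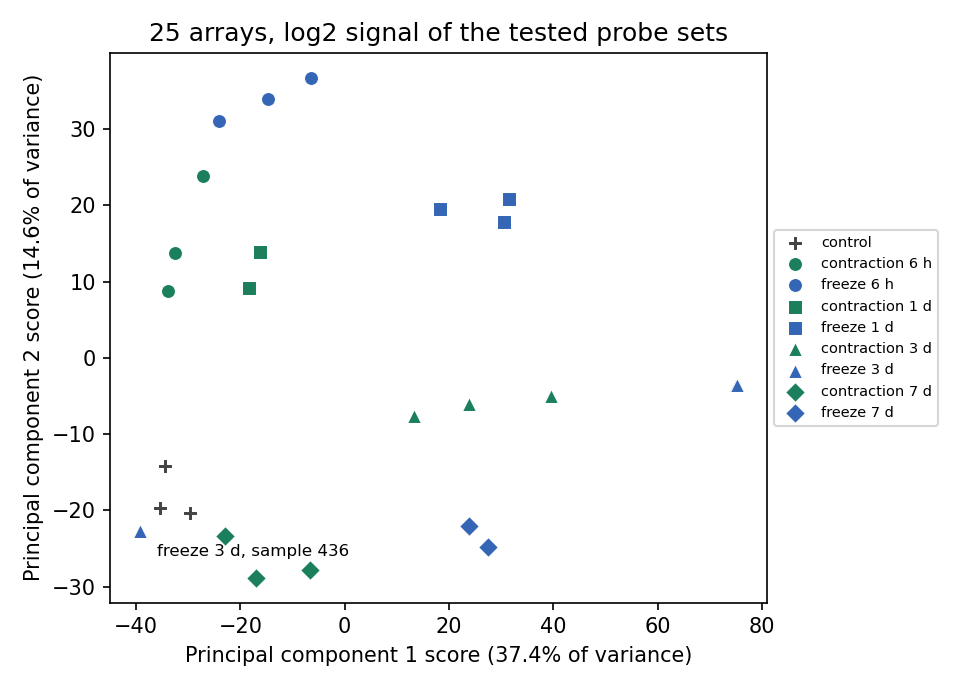
Scores of the 25 arrays on principal component 1 (x axis, 37.4% of variance) and principal component 2 (y axis, 14.6%) of the log2 signals of the tested probe sets, 1 point per array. Sample 436 lies at -39.2 on the x axis, beside the controls at -35.4 to -29.6, and the other 2 arrays of its group overlap at 75.1 and 75.2.

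Of 9506 probe sets tested, 2491 changed after injury in at least 1 of the 8 injured groups by limma's moderated F test, and 4686 did without sample 436. Contraction changed 178 probe sets at 6 hours, 170 at 1 day, 784 at 3 days and 51 at 7 days, while freeze changed 461, 1351, 1698 and 503, more at each time. At 3 days this order turns at an adjusted p under 0.01, with 167 calls for contraction and 75 for freeze. It also turns there with only the compared groups in the fit, with 1215 for contraction and 0 for freeze, which had 1328 at an unadjusted p under 0.05 by limma. Without sample 450 the counts of contraction and freeze at 3 days were 1048 and 7, and without 468 they were 991 and 12. Without sample 440 both injuries gave 42 at 7 days. Without sample 436 the counts over the 4 times were 319, 412, 2163 and 288 for contraction and 1083, 2544, 4029 and 1855 for freeze. These counts also depend on group size, which was 2 for contraction at 1 day and for freeze at 7 days. Whether single genes differed between the injuries is tested further on.

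**Figure D2:**
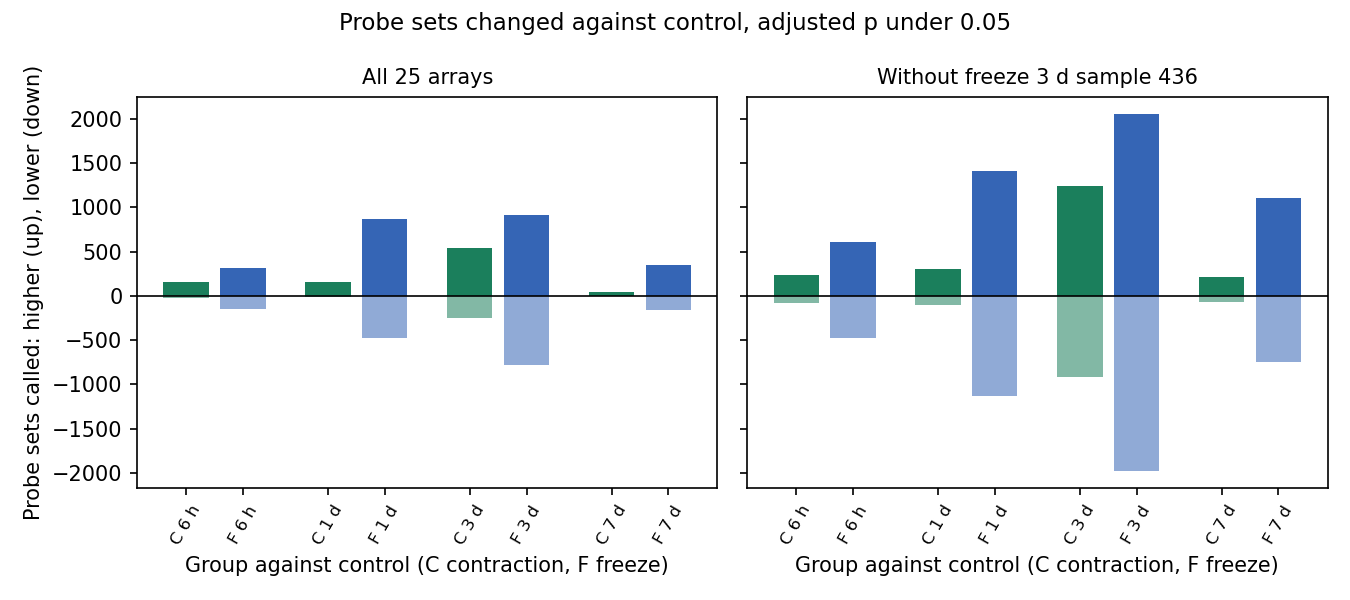
Probe sets called at an adjusted p under 0.05 in each injured group against control, with all 25 arrays (left) and without sample 436 (right). Bars above 0 count probe sets that were higher and paler bars below 0 those that were lower. The largest bars are those of freeze at 3 days, with 920 higher and 778 lower, or 2053 and 1976 without that sample.

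At 6 hours after contraction injury, stress response genes led the rises. The inducible Hsp70 chaperone genes Hspa1b and Hspa1a rose 246-fold (log2 7.94 ± 0.67, adjusted p = 4.09e-08) and 170-fold (log2 7.41 ± 0.55, adjusted p = 5.93e-09), and their co-chaperone gene Dnajb1 rose 56.6-fold. Hspa1a signal went from 79.0 ± 33.2 in controls to 15256 ± 4207 (SD, n = 3 each). Among heat shock and chaperone genes, 13 of 18 rose (15 adjusted over the list alone), with a median of 2.24 (adjusted p = 1.52e-39). Of immediate early and stress transcription factors, 17 of 26 rose (19 adjusted over the list alone, list test adjusted p = 7.22e-47), with Fos (6.75) and Atf3 (6.35) ahead. Genes induced by mechanical load rose as well, namely Ankrd1 (5.74) and Xirp1 (4.22), and of the list of sarcomere strain and membrane repair 5 of 18 rose (6 adjusted over the list alone, list test adjusted p = 1.14e-07). Within the antioxidant and metal list 3 of 21 rose (3 adjusted over the list alone, list test adjusted p = 0.00311, but adjusted p = 0.0414 with an estimated correlation), led by Srxn1 (5.13) and Mt2 (4.55). Of the cytokines and chemokines 3 of 23 rose (7 adjusted over the list alone), with Ccl2 (3.68) and Cxcl1 (2.10) highest (adjusted p = 1.87e-05, but adjusted p = 0.342 with an estimated correlation). Of the growth factors and receptors 3 of 29 rose (3 adjusted over the list alone, list test adjusted p = 0.00228), among them Ccn1 (4.05) and Hbegf (2.23). The myogenic factor genes Myod1 (2.83) and Myf6 (2.87) rose. The largest falls named by rule were in the clock output gene Dbp (-1.97 ± 0.40, adjusted p = 0.00688), then Tarbp2 (-1.55) and Adcy3 (-1.36). Rises without sample 436, with estimated-correlation adjusted p in brackets, numbered 4 of 21 antioxidant and metal genes (0.0812) and 6 of 23 cytokine and chemokine genes (0.0812). The rule then also named Necap2 (-1.34) among the falls. Of the 178 probe sets called, 155 were higher and 23 lower; without sample 436 there were 240 and 79.

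At 1 day after contraction the highest genes were Hspa1b (8.00), Hspa1a (7.14), Fos (5.85), Atf3 (5.65) and Ankrd1 (5.31), of which the first 4 were also among the 5 highest at 6 hours. Of the heat shock list 15 of 18 rose (16 adjusted over the list alone, list test adjusted p = 2.2e-35). Of the immediate early list 14 of 26 rose (19 adjusted over the list alone, list test adjusted p = 1.16e-30). In the sarcomere strain list 6 of 18 rose (7 adjusted over the list alone, list test adjusted p = 6.43e-11), with Csrp3 (4.20), a gene of a Z-disc protein, second to Ankrd1. Of nucleolar genes 0 of 22 rose (1 adjusted over the list alone, 5 at an unadjusted p under 0.05 by limma) at a median of 0.41 (adjusted p = 8.22e-05, but adjusted p = 0.304 with an estimated correlation), and proteasome genes had a median of 0.22 with 0 rises among 32 members (0 adjusted over the list alone, 5 at an unadjusted p under 0.05 by limma, list test adjusted p = 0.00416, but adjusted p = 0.526 with an estimated correlation). Among macrophage markers 0 of 27 rose (0 adjusted over the list alone, 2 at an unadjusted p under 0.05 by limma, list test adjusted p = 0.00726, but adjusted p = 0.875 with an estimated correlation). The myelin gene Mbp (-1.08) fell, and of the Schwann cell and nerve markers 1 of 7 fell (1 adjusted over the list alone, list test adjusted p = 0.0281, but adjusted p = 0.354 with an estimated correlation). The falls named by rule were Gm13205 (-1.92), Pik3r2 (-1.56), Ap5s1 (-1.46), Gpr19 (-1.32) and Rabggta (-1.16). Rises without sample 436, with estimated-correlation adjusted p in brackets, numbered 2 of 22 nucleolar genes (0.206), 1 of 32 proteasome genes (0.492) and 5 of 27 macrophage markers (0.198). The rule then also named Wnt4 (-2.07), Gdap1 (-1.65) and Pptc7 (-1.52) among the falls. The call count was 155 higher and 15 lower, and 309 and 103 without sample 436. It was 97 without sample 421 and 65 without sample 463, which leaves 1 array.

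Freeze injury at 6 hours raised chemokine and neutrophil genes beside the early stress genes. Rrad, a small GTPase gene, rose 86.3-fold (log2 6.43 ± 0.61, adjusted p = 3.55e-07), the monocyte chemokine gene Ccl2 rose 70.9-fold (6.15 ± 0.86, adjusted p = 5.7e-05) and metallothionein Mt1 60.4-fold. Of the cytokines and chemokines 13 of 23 rose (16 adjusted over the list alone), at a median of 1.76 (adjusted p = 1.9e-14, but adjusted p = 0.045 with an estimated correlation). Among them were Ccl2 (6.15), Cxcl5 (4.72) and the interleukin gene Il6 (4.00). The neutrophil genes S100a9 (5.52) and S100a8 (5.47) rose, and 5 of 10 rose (5 adjusted over the list alone) in their list (adjusted p = 0.000156, but adjusted p = 0.0624 with an estimated correlation), whereas granule genes Mpo and Camp had values of -0.97 and -0.54 and were not called. Heat shock genes Hspa1b (5.81) and Hspa1a (5.74) rose too, and 9 of 18 rose (14 adjusted over the list alone) in the list (adjusted p = 9.56e-13, but adjusted p = 0.0184 with an estimated correlation). In the immediate early list 19 of 26 rose (21 adjusted over the list alone, list test adjusted p = 3.88e-39). In the sarcomere strain list 5 of 18 rose (5 adjusted over the list alone) and 1 fell (1, list test adjusted p = 0.000826), with Ankrd1 (5.47) and Xirp1 (3.94) up and Dag1 (-0.78) down. Of the macrophage markers 3 of 27 rose (3 adjusted over the list alone, list test adjusted p = 2.53e-05, but adjusted p = 0.693 with an estimated correlation), among them Cd53 (4.23) and Tyrobp (3.58). Matrix protease genes Adam8 (3.67) and Mmp3 (3.18) rose, and in their list 5 of 20 rose (6 adjusted over the list alone, list test adjusted p = 0.000156, but adjusted p = 0.36 with an estimated correlation). The myogenic factors Myod1 (3.20) and Myf6 (3.02) rose. Dbp fell by 3.36 ± 0.40 (adjusted p = 7.67e-06), followed by Crebbp (-1.96), Septin4 (-1.78), Ogn (-1.62) and Six4 (-1.54). Without sample 436 the rule also named Wnt4 (-1.72) among the falls, and rises numbered 14 of 27 macrophage markers (0.0634), with estimated-correlation adjusted p in brackets. The calls comprised 317 higher and 144 lower probe sets, or 610 and 473 without sample 436. Without sample 446 the count was 273, and without control 3 it was 299.

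By 1 day after freeze, macrophage, chemokine and early stress genes were high, and genes of fibre metabolism were low. In the immediate early list 15 of 26 rose (17 adjusted over the list alone), at a median of 0.97. Its list test adjusted p was 8.11e-09, but 0.0284 with an estimated correlation. With all arrays it alone of the lists called in this group kept its call with an estimated correlation. Ccl2 was 115-fold up (6.85 ± 0.86, adjusted p = 2.9e-05), Arg1, arginase 1, 54.4-fold (5.77 ± 0.43, adjusted p = 4.83e-08) and Ccl9 (5.52), Mt2 (5.45) and Mt1 (5.42) followed. Of the macrophage markers 19 of 27 rose (22 adjusted over the list alone), at a median of 2.54 (adjusted p = 9.35e-13, but adjusted p = 0.301 with an estimated correlation), with Cd53 (5.16), Tyrobp (5.13) and Cd68 (3.36). Cytokine and chemokine genes gave 13 rises among 23 members (17 adjusted over the list alone, list test adjusted p = 1.31e-10, but adjusted p = 0.152 with an estimated correlation). Neutrophil genes gave 4 rises among 10 members (5 adjusted over the list alone, list test adjusted p = 0.0232, but adjusted p = 0.344 with an estimated correlation). Of the lymphocyte markers 2 of 12 fell (3 adjusted over the list alone, list test adjusted p = 0.0147, but adjusted p = 0.151 with an estimated correlation), namely Cd4 (-1.46) and Ighm (-1.13). Of nucleolar genes 11 of 22 rose (12 adjusted over the list alone, list test adjusted p = 1.17e-08, but adjusted p = 0.151 with an estimated correlation). Of cell cycle genes 9 of 40 rose (10 adjusted over the list alone, list test adjusted p = 4.33e-05, but adjusted p = 0.475 with an estimated correlation), with Cks1b (2.86) and Cdk1 (2.13). Heat shock genes gave 7 rises among 18 members (7 adjusted over the list alone, list test adjusted p = 0.00198, but adjusted p = 0.369 with an estimated correlation), with Hsp90aa1 (2.83) and Hspa5 (2.23) ahead, and Hspa1b had a value of 2.17. Of fast fibre genes 4 of 23 fell (5 adjusted over the list alone, list test adjusted p = 0.00561, but adjusted p = 0.532 with an estimated correlation), among them Clcn1 (-1.65) and Kcna7 (-1.53). In the glycolysis and glycogen list 5 of 18 fell (7 adjusted over the list alone, list test adjusted p = 0.000146, but adjusted p = 0.475 with an estimated correlation). In that of the TCA cycle and fatty acid oxidation 4 of 34 fell (20 adjusted over the list alone, list test adjusted p = 8.66e-07, but adjusted p = 0.475 with an estimated correlation). The largest single falls were Ces1d (-3.34), Rxrg (-2.52), Gdap1 (-2.51), Eepd1 (-2.46) and Wnt4 (-2.43). Rises without sample 436, with estimated-correlation adjusted p in brackets, numbered 26 of 27 macrophage markers (0.0168) and 15 of 40 cell cycle genes (0.0922), and falls 4 of 12 lymphocyte markers (0.179), 14 of 23 fast fibre genes (0.203, with 1 rising), 13 of 18 glycolysis and glycogen genes (0.1) and 27 of 34 TCA cycle and fatty acid oxidation genes (0.117). The neutrophil list, with 4 rises and 1 fall, then did not pass the list test (adjusted p = 0.0721). The actin 3'/5' ratio was 1.01 to 1.31 on these 3 arrays, against 0.560 to 0.595 in controls. The calls were 870 higher and 481 lower, or 1408 and 1136 without sample 436. They came to 820 without sample 460, 684 without 464, 866 without control 1 and 890 without control 3.

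By 3 days after contraction injury, macrophage and proliferation genes were high and metabolic genes low, on arrays whose actin 3'/5' ratio was 0.923 to 1.21. Lgals3 rose 52.7-fold (5.72 ± 1.02, adjusted p = 0.00282), Apoe 39.1-fold (5.29 ± 1.34) and cathepsin S, Ctss, 32.8-fold, while Lyz2 (4.86) and Ankrd1 (4.85) completed the highest 5. In the sarcomere strain list 7 of 18 rose (9 adjusted over the list alone) and 0 fell (1), at a median of 0.58. Its list test adjusted p was 0.000186, but 0.0175 with an estimated correlation. With all 25 arrays it alone of the lists called in this group kept its call with an estimated correlation. Without sample 436 that list had 8 rises and 2 falls (adjusted p = 0.0166 with an estimated correlation). Of the macrophage markers 17 of 27 rose (25 adjusted over the list alone), at a median of 2.52 (adjusted p = 3.19e-14, but adjusted p = 0.224 with an estimated correlation). In the cell cycle list 12 of 40 rose (21 adjusted over the list alone, list test adjusted p = 1.8e-10, but adjusted p = 0.237 with an estimated correlation), with Stmn1 (3.21) and Cks1b (2.71). Of myogenic genes 9 of 27 rose (16 adjusted over the list alone) and 1 fell (1, list test adjusted p = 8.59e-07, but adjusted p = 0.151 with an estimated correlation), with the acetylcholine receptor gene Chrna1 (3.58) and the differentiation factor Myog (2.88), while Actc1 (-1.31) fell. Protease genes gave 8 rises among 20 members (11 adjusted over the list alone, list test adjusted p = 3.41e-05, but adjusted p = 0.237 with an estimated correlation), led by Mmp12 (4.83) and Adam8 (3.25). Hsp70 genes Hspa1a (4.21) and Hspa1b (4.09) rose, and 8 of 18 rose (9 adjusted over the list alone) in their list (adjusted p = 4.27e-06, but adjusted p = 0.181 with an estimated correlation). Of TCA cycle and fatty acid oxidation genes 10 of 34 fell (28 adjusted over the list alone, list test adjusted p = 6.97e-12, but adjusted p = 0.237 with an estimated correlation), with Eci1 (-1.54) and Acadm (-1.51). Of glycolysis and glycogen genes 4 of 18 fell (13 adjusted over the list alone, list test adjusted p = 3.44e-07, but adjusted p = 0.309 with an estimated correlation), led by Gpd1 (-2.93), and of oxidative phosphorylation genes 2 of 42 fell (12 adjusted over the list alone) and 1 rose (1), the riser being Cox6a1 (1.16), a subunit isoform of cytochrome oxidase found in many tissues (adjusted p = 1.59e-07, but adjusted p = 0.385 with an estimated correlation). Proteasome genes gave 6 rises among 32 members (11 adjusted over the list alone, list test adjusted p = 3.49e-06, but adjusted p = 0.181 with an estimated correlation). Interferon genes had a median of 0.69 with 0 rises among 24 members (0 adjusted over the list alone, 6 at an unadjusted p under 0.05 by limma, list test adjusted p = 0.00161, but adjusted p = 0.479 with an estimated correlation). Fast fibre genes had a median of -0.83, and 1 of 23 fell (1 adjusted over the list alone) and 1 rose (1, list test adjusted p = 0.00155, but adjusted p = 0.479 with an estimated correlation). The remaining falls named by rule were Wnt4 (-2.58), Smyd2 (-2.44), Ptp4a3 (-2.30) and Slc37a4 (-2.10). Rises without sample 436, with estimated-correlation adjusted p in brackets, numbered 25 of 27 macrophage markers (0.0166), 25 of 40 cell cycle genes (0.0166), 16 of 27 myogenic genes (0.046, with 1 falling), 12 of 20 protease genes (0.051, with 1 falling), 11 of 32 proteasome genes (0.196, with 1 falling) and 11 of 24 interferon genes (0.188). Falls then numbered 30 of 34 TCA cycle and fatty acid oxidation genes (0.046), 15 of 18 glycolysis and glycogen genes (0.046), 31 of 42 oxidative phosphorylation genes (0.108, with 1 rising) and 15 of 23 fast fibre genes (0.131, with 1 rising), and the rule also named Phf7 (-2.29). The calls were 539 higher and 245 lower, or 1242 and 921 without sample 436. Without sample 435 the count was 227, without 467 it was 277, and without control 1, 2 or 3 it was 358, 522 or 306.

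At 3 days after freeze, macrophage, interferon and cell cycle genes were high, and genes of contraction and energy metabolism were low. These shifts were carried by samples 450 and 468, while sample 436 lay among the controls. With all 3 arrays, the genes with the largest rises that kept every freeze array beyond every control were Ifi30 (3.61), Ifit2 (3.46), Lgmn (2.96), Lat2 (2.85) and Usp18 (2.83), and those with the largest falls were Hrc (-2.32), Coq10a (-2.31), Ldb3 (-2.22), Adam28 (-2.19) and Smyd1 (-2.16). Without sample 436 the leading rises were Apoe (6.75), Tyrobp (6.70), Lgals3 (6.55), Ctss (6.26) and Cd53 (6.19) and the leading falls Ptp4a3 (-3.62), Slc2a4 (-3.52), Sh3bgr (-3.48), Phkg1 (-3.44) and Cox7a1 (-3.40), Slc2a4 being the insulin-responsive glucose transporter and Cox7a1 a muscle isoform of a cytochrome oxidase subunit. Of the macrophage markers 23 of 27 rose (25 adjusted over the list alone) at a median of 2.66 (adjusted p = 7.19e-13, but adjusted p = 0.411 with an estimated correlation). Without sample 436, 26 rose at a median of 4.20 (adjusted p = 9.94e-22, but adjusted p = 0.026 with an estimated correlation). Of the interferon response genes 12 of 24 rose (18 adjusted over the list alone, list test adjusted p = 1.45e-09, but adjusted p = 0.411 with an estimated correlation), with Ifit2 (3.46) and Usp18 (2.83) ahead. Without the sample 24 of 24 rose (adjusted p = 5.12e-13, but adjusted p = 0.0472 with an estimated correlation). The cell cycle list gave 19 rises among 40 members (31 adjusted over the list alone, list test adjusted p = 3.8e-12, but adjusted p = 0.411 with an estimated correlation). It gave 36 without the sample (adjusted p = 4.1e-13, but adjusted p = 0.026 with an estimated correlation). Of the fast fibre list 11 of 23 fell (18 adjusted over the list alone) and 1 rose (1, list test adjusted p = 4.41e-06, but adjusted p = 0.411 with an estimated correlation). Of glycolysis 12 of 18 fell (14 adjusted over the list alone, list test adjusted p = 3.59e-07, but adjusted p = 0.411 with an estimated correlation). Of oxidative phosphorylation 18 of 42 fell (37 adjusted over the list alone) and 1 rose (1, list test adjusted p = 5.5e-10, but adjusted p = 0.411 with an estimated correlation). Of the TCA cycle and fatty acid oxidation 25 of 34 fell (31 adjusted over the list alone, list test adjusted p = 3.8e-12, but adjusted p = 0.411 with an estimated correlation). Without sample 436 there were 20, 18, 38 and 32 falls in these 4 lists, and their medians were -2.30, -2.39, -1.68 and -1.72, with estimated-correlation adjusted p values of 0.0487, 0.0472, 0.0533 and 0.0487. The exceptions Cox6a1 (1.38) and Tpm1 (1.23), of which Tpm1 encodes a tropomyosin also made outside muscle, rose. The embryonic myosin gene Myh3 (3.18) and Myog (2.66) rose, and in the myogenic list 9 of 27 rose (11 adjusted over the list alone) and 2 fell (4, list test adjusted p = 0.00692, but adjusted p = 0.411 with an estimated correlation). That list had 14 rises and 5 falls without the sample (adjusted p = 0.227 with an estimated correlation). The median over all tested probe sets was -0.09, and -0.12 without sample 436, to which the values of this group are relative. The calls were 920 higher and 778 lower, or 2053 and 1976 without the sample. The count was 7 without sample 450, 12 without 468, and 697, 1060 or 699 without control 1, 2 or 3.

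By 7 days after contraction injury genes of developing and slow muscle led the rises. The embryonic and atrial light chain gene Myl4 rose 20.4-fold (4.35 ± 0.52, adjusted p = 7.95e-05), the embryonic myosin gene Myh3 13.1-fold (3.71 ± 0.71, adjusted p = 0.0135), and Tnnt1 (3.61), Tnni1 (3.51) and Myh8 (3.33) followed. Of the myogenic list 7 of 27 rose (12 adjusted over the list alone, list test adjusted p = 3.37e-17). In the slow fibre list 3 of 9 rose (4 adjusted over the list alone, list test adjusted p = 0.00209, but adjusted p = 0.0561 with an estimated correlation), with Tnnt1 (3.61), Tnni1 (3.51) and Atp2a2 (2.29), while Myl3, a slow light chain gene, had a value of -2.05. Of proteasome genes 1 of 32 rose (10 adjusted over the list alone) at a median of 0.42 (adjusted p = 2.62e-13, but adjusted p = 0.0368 with an estimated correlation). Of endothelial and pericyte markers 2 of 18 fell (4 adjusted over the list alone) at a median of -0.54 (adjusted p = 1.79e-08), with Kcnj8 (-1.56) and Tie1 (-1.08), and Aqp1 (-1.40) and Atf5 (-1.02) were the other falls named by rule. The growth factor gene Igf2 (2.64) rose. Of the macrophage markers 0 of 27 rose (1 adjusted over the list alone, 2 at an unadjusted p under 0.05 by limma, list test adjusted p = 0.00209, but adjusted p = 0.75 with an estimated correlation). With sample 436 left out the rises, with estimated-correlation adjusted p in brackets, numbered 11 of 27 myogenic genes (0.00295), 4 of 9 slow fibre genes (0.0615, with 1 falling), 5 of 32 proteasome genes (0.0606) and 8 of 27 macrophage markers (0.106). The rule then also named Lgals3 (4.34) among the rises and Myl3 (-2.05), Plin4 (-1.52) and Ptp4a3 (-1.41) among the falls. The calls were 45 higher and 6 lower, or 213 and 75 without sample 436. Leaving out sample 425, 439 or 453 gave 30, 13 or 13 calls, and leaving out control 1, 2 or 3 gave 25, 22 or 23.

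At 7 days after freeze, genes of developing muscle, matrix and macrophages were high. Apoe rose 56.9-fold (5.83 ± 1.5, adjusted p = 0.0282), Myh3 56.5-fold (5.82 ± 0.79, adjusted p = 0.000174) and periostin, Postn, 45.4-fold (5.51 ± 0.90, adjusted p = 0.00147), followed by Myh8 (4.96) and Myl4 (4.82). Of the extracellular matrix genes 25 of 34 rose (30 adjusted over the list alone, list test adjusted p = 4.76e-20, but adjusted p = 0.092 with an estimated correlation) at a median of 1.53, among them Col5a2 (4.47), Tnc (3.99), Col3a1 (3.80) and Col1a1 (3.27). Fibroblast markers gave 9 rises among 18 members (14 adjusted over the list alone, list test adjusted p = 3.51e-10, but adjusted p = 0.092 with an estimated correlation), led by Mfap2 (3.10) and S100a4 (2.71). Of the myogenic list 12 of 27 rose (19 adjusted over the list alone, list test adjusted p = 1.37e-13, but adjusted p = 0.0245 with an estimated correlation). Of the slow fibre list 4 of 9 rose (4 adjusted over the list alone, list test adjusted p = 0.00173, but adjusted p = 0.092 with an estimated correlation). Macrophage markers gave 8 rises among 27 members (18 adjusted over the list alone, list test adjusted p = 2.2e-09, but adjusted p = 0.391 with an estimated correlation), with Lyz2 (4.68) and Ctss (4.54). MHC class II genes gave 3 rises among 9 members (5 adjusted over the list alone, list test adjusted p = 0.0163, but adjusted p = 0.433 with an estimated correlation). Complement genes gave 1 rise among 8 members (1 adjusted over the list alone, list test adjusted p = 0.0339, but adjusted p = 0.368 with an estimated correlation). Interferon genes gave 1 rise among 24 members (7 adjusted over the list alone, list test adjusted p = 1.71e-05, but adjusted p = 0.435 with an estimated correlation). Of glycolysis and glycogen genes 0 of 18 fell (0 adjusted over the list alone, 8 at an unadjusted p under 0.05 by limma) at a median of -0.78 (adjusted p = 0.000113, but adjusted p = 0.435 with an estimated correlation). The largest falls were Ces1d (-3.01), Ptp4a3 (-2.70), Plin4 (-2.50), Tspan8 (-2.46) and Egln1 (-2.27). With sample 436 left out the rises, with estimated-correlation adjusted p in brackets, numbered 29 of 34 matrix genes (0.0147), 14 of 18 fibroblast markers (0.0147), 18 of 27 myogenic genes (0.0147, with 1 falling), 4 of 9 slow fibre genes (0.0816, with 1 falling), 22 of 27 macrophage markers (0.0171), 5 of 9 MHC class II genes (0.0816), 3 of 8 complement genes (0.0893) and 14 of 24 interferon genes (0.0816). Falls then numbered 12 of 18 glycolysis and glycogen genes (0.0816). The calls were 347 higher and 156 lower, or 1111 and 744 without sample 436. The group held 2 arrays, and the count was 42 without sample 440 and 54 without 454. It was 233 without control 1 and 150 without control 3.

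**Figure D3:**
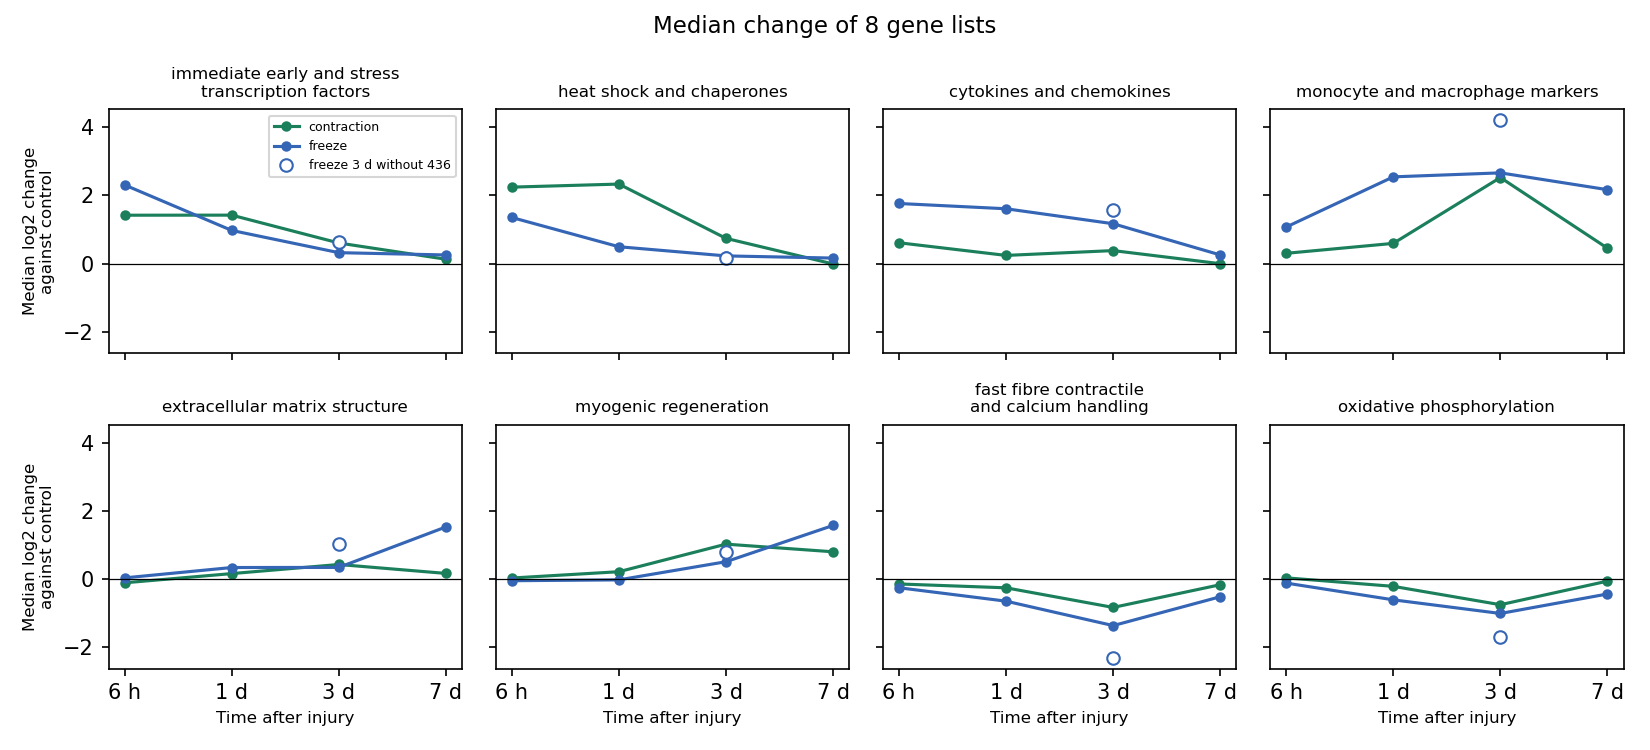
Median log2 change against control (y axis) of the measured members of 8 gene lists at each time (x axis) for contraction (green) and freeze (blue), from all 25 arrays. Open circles give freeze at 3 days without sample 436, where the macrophage list reached 4.20 and the fast fibre list -2.30.

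Calls of the 2 injuries overlapped at each time. At 6 hours 112 probe sets were higher and 9 lower in both, against 5.17 and 0.348 for independent lists. The numbers were 95 and 7 at 1 day (independent 14.2 and 0.759), 373 and 147 at 3 days (52.2 and 20.1) and 36 and 4 at 7 days (1.64 and 0.0985). Without sample 436 they were 191 and 46, 226 and 84, 1099 and 787, and 180 and 52. Independent lists would then share more too, namely 15.4 and 3.93, 45.8 and 12.3, 268 and 191, and 24.9 and 5.87. Both sets were compared with the same 3 controls, too few to give each injury at least 2 of its own, so part of the excess may come from them. In 100 simulations of unchanged groups against these controls no probe set was shared, but unchanged groups give few calls to share, so this does not bound the part from the controls. The correlation of fold changes across probe sets was 0.74, 0.61, 0.86 and 0.68 at the 4 times, against 0.50, 0.45, 0.50 and 0.45 in simulation, and the covariance was 0.245, 0.266, 0.482 and 0.221 against 0.0614, 0.0619, 0.0620 and 0.0619. Probe sets are not independent replicates. The overlap at 3 days was 5 without sample 450 and 10 without 468, 150 without 435, 193 without 467, and 180, 298 or 149 without control 1, 2 or 3. At 7 days it was 26, 12 or 13 without samples 425, 439 or 453, 17 or 16 without 440 or 454, and 23, 19 or 14 without control 1, 2 or 3. At 1 day it was 62 without sample 421 and 43 without 463.

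Tested directly at 6 hours, freeze exceeded contraction in neutrophil and chemokine genes and was below it in the chaperone gene Dnajb1. The calprotectin genes S100a9 and S100a8 were 11.7-fold (3.55 ± 0.63, adjusted p = 0.0207) and 11-fold higher after freeze, with Il1b (3.29), Cxcl5 (2.95), Hdc (2.60), Cxcl2 (2.28), Bcl3 (2.26) and Mmp3 (2.22) next. Of the cytokines and chemokines 4 of 23 were higher (15 adjusted over the list alone, list test adjusted p = 8.14e-12, but adjusted p = 0.19 with an estimated correlation). Of the neutrophil markers 3 of 10 were higher (4 adjusted over the list alone, list test adjusted p = 0.00463, but adjusted p = 0.34 with an estimated correlation). Lower after freeze were Dnajb1 (-3.64), Enah (-1.74), Jun (-1.51) and Sesn1 (-1.40). In the heat shock list 1 of 18 was lower (12 adjusted over the list alone), at a median of -1.15 (adjusted p = 2.74e-14, but adjusted p = 0.051 with an estimated correlation). Without sample 436, with estimated-correlation adjusted p in brackets, 11 of 23 cytokine and chemokine genes (0.055) were higher and 6 of 18 heat shock genes (0.0711) lower. The rule then also named Cd53 (3.38), Adam8 (3.28), Slfn4 (3.09) and Lilr4b (2.74) among the higher and Hsp90aa1 (-1.75), Rag1 (-1.52), Dbp (-1.39) and Crebbp (-1.39) among the lower genes. The calls were 24 higher and 5 lower, or 172 and 52 without sample 436. The count was 1, 49 or 2 without samples 417, 431 or 445 and 4, 83 or 0 without 418, 432 or 446. It was 16 or 17 without any one of 422, 460, 464, 440 or 454, and 19 without 439.

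At 1 day chaperone genes were lower after freeze, and the calprotectin genes S100a8 and S100a9 and chemokine genes higher. Lower after freeze were Hspa1b (-5.83 ± 0.75, adjusted p = 9.43e-05), Hspa1a (-5.28 ± 0.62, adjusted p = 3.88e-05) and Dnajb1 (-4.98 ± 0.80). Hspa1a signal was 12384 ± 1059 (SD, n = 2) after contraction and 312 ± 72.0 (SD, n = 3) after freeze. Of the heat shock list 11 of 18 were lower (14 adjusted over the list alone, list test adjusted p = 8.15e-17, but adjusted p = 0.0129 with an estimated correlation). Also lower were Mmp10 (-3.87), Fos (-3.55), Mybph (-3.46), Dnajb4 (-3.23) and Atf3 (-3.06), and in the sarcomere strain list 2 of 18 were lower (8 adjusted over the list alone, list test adjusted p = 5.74e-05), with Enah (-2.77) and Csrp3 (-2.24). Higher after freeze were S100a8 (4.43), Arg1 (4.27), S100a9 (4.16), Slfn4 (3.80), Il1b (3.43), Cxcl5 (3.36), Mmp9 (3.28) and Ccl7 (3.06). Cytokine and chemokine genes gave 5 higher members of 23 (13 adjusted over the list alone, list test adjusted p = 9.07e-12, but adjusted p = 0.129 with an estimated correlation). Macrophage markers had a median of 1.93 with 1 higher member of 27 (14 adjusted over the list alone, list test adjusted p = 2.39e-11, but adjusted p = 0.317 with an estimated correlation). Without sample 436, with estimated-correlation adjusted p in brackets, 14 of 23 cytokine and chemokine genes (0.0293) and 24 of 27 macrophage markers (0.0209) were higher and 14 of 18 heat shock genes (0.0293, with 1 higher) and 8 of 18 sarcomere strain genes (0.0209, with 3 higher) lower. The rule then also named Adam8 (3.87), Cd53 (3.50) and Tyrobp (3.48) among the higher genes. The actin 3'/5' ratio was 1.01 to 1.31 on the freeze and 0.617 to 0.641 on the contraction arrays. The calls were 68 higher and 70 lower, or 610 and 354 without sample 436. They numbered 42 without sample 421, 22 without 463, and 72, 74 or 66 without 422, 460 or 464.

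At 3 days, with sample 436 in the group, 4 probe sets were higher and 33 lower after freeze. The lowest was Hspa1a (-4.18 ± 0.55, adjusted p = 0.000519), followed by Hspa1b (-3.48), Rrad (-2.79), Csrp3 (-2.61), Ankrd1 (-2.57), Ankrd2 (-2.28), Plet1 (-2.21) and Rgcc (-2.03), and the higher genes named by rule were Pla2g7 (1.52), Gpx3 (1.2) and Creg1 (1.13). In the sarcomere strain list 4 of 18 were lower (8 adjusted over the list alone, list test adjusted p = 3.85e-13). In the heat shock list 4 of 18 were lower (4 adjusted over the list alone, list test adjusted p = 3e-06, but adjusted p = 0.237 with an estimated correlation). Without sample 436 the counts were 841 and 770. Then Plac8 (3.40), Sfrp2 (3.21), Ifit2 (3.13), Napsa (2.99), Tgfb1 (2.74), Mx1 (2.69), Slfn4 (2.67) and Ifit3 (2.65) were highest after freeze, and Hspa1a (-4.37), Hspa1b (-3.41), Adcy2 (-2.66), Csrp3 (-2.65), Xirp1 (-2.52), Cox7a1 (-2.39), Ankrd2 (-2.36) and Rgcc (-2.25) lowest. The sarcomere strain list then had 10 lower members and 1 higher, and the heat shock list 6 lower and 1 higher. Interferon genes then gave 20 higher members of 24 (22 adjusted over the list alone, list test adjusted p = 6.49e-18, but adjusted p = 0.0199 with an estimated correlation). Macrophage markers gave 20 higher members of 27 (23 adjusted over the list alone, list test adjusted p = 3.7e-15, but adjusted p = 0.0436 with an estimated correlation). Fast fibre genes gave 17 lower members of 23 (19 adjusted over the list alone) and 1 higher (1, list test adjusted p = 1.6e-13, but adjusted p = 0.0436 with an estimated correlation). Oxidative phosphorylation genes gave 31 lower members of 42 (36 adjusted over the list alone) and 1 higher (1, list test adjusted p = 1e-15, but adjusted p = 0.0708 with an estimated correlation). With all arrays the macrophage list had a median of 0.05 (adjusted p = 0.707). Then 0 of 24 interferon genes were higher, and 1 of 23 fast fibre and 0 of 42 oxidative phosphorylation genes lower. By camera the adjusted p of these 3 lists was 1.29e-08, 0.00517 and 0.0221. With an estimated correlation it was 0.42, 0.799 and 0.881. The myogenic list was lower with all arrays, at -0.22 (adjusted p = 0.0171, but adjusted p = 0.44 with an estimated correlation), and had the opposite sign, 0.19, without sample 436 (adjusted p = 0.76). The count of calls was 23 without sample 435, 14 without 467, and 19 without 450 or without 468.

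At 7 days matrix and fibroblast genes were higher after freeze. Tenascin C, Tnc, was 10.8-fold higher (3.43 ± 0.66, adjusted p = 0.0218), with signals of 570 ± 45.5 (SD, n = 2) after freeze, 41.8 ± 10.5 (SD, n = 3) after contraction and 30.0 ± 28.7 (SD, n = 3) in controls. Next were Dlk1 (2.55), Ccn3 (2.42), Chpf (2.35), Col6a3 (2.34), P3h3 (2.31), Dpt (2.26) and Arsa (2.19). Of the matrix genes 8 of 34 were higher (31 adjusted over the list alone) at a median of 1.33 (adjusted p = 7.8e-29, but adjusted p = 0.0489 with an estimated correlation). Of the fibroblast markers 4 of 18 were higher (15 adjusted over the list alone, list test adjusted p = 3.14e-16, but adjusted p = 0.0489 with an estimated correlation). Endothelial and pericyte markers had a median of 0.68, and 1 of 18 was higher (2 adjusted over the list alone, list test adjusted p = 2.85e-06, but adjusted p = 0.0337 with an estimated correlation). Macrophage markers gave 0 higher members of 27 (0 adjusted over the list alone, 9 at an unadjusted p under 0.05 by limma) at a median of 1.41 (adjusted p = 3.81e-07, but adjusted p = 0.47 with an estimated correlation). Without sample 436, with estimated-correlation adjusted p in brackets, 28 of 34 matrix genes (0.00538), 13 of 18 fibroblast markers (0.00538), 2 of 18 endothelial and pericyte markers (0.0547) and 20 of 27 macrophage markers (0.038) were higher. The highest genes named by rule then also included Postn (3.40), Csrp2 (3.37), Col5a2 (3.27), Lyz2 (3.01), Cd53 (2.91), Col3a1 (2.87) and Col1a2 (2.84), and the lowest were Tspan8 (-1.94), Ces1d (-1.90), Slc25a45 (-1.81), Gpr12 (-1.60), Cmbl (-1.56), Bcl2l10 (-1.53), Aldh1a1 (-1.53) and Oaz3 (-1.52). All 35 probe sets called were higher after freeze. By limma 1028 probe sets had an unadjusted p under 0.05, in either direction, and without sample 436 the calls were 536 higher and 155 lower. The count was 8 or 9 without samples 425 or 453, 7 or 10 without 440 or 454, and 61 or 62 without 450 or 468.

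Averaged over the 4 times, 386 probe sets were higher after freeze and 195 lower, or 1618 and 1321 without sample 436. With each array centred on its median the split was 315 and 245. The highest named genes were Slfn4 (2.25), Adam8 (2.19), Il1b (2.06), Tyrobp (2.01), Lst1 (1.95), Slfn2 (1.93), Cxcl5 (1.93) and Fcgr2b (1.80), of which Tyrobp encodes an adaptor of myeloid receptors and Fcgr2b an antibody receptor. The lowest were Hspa1a (-2.79 ± 0.29, adjusted p = 1.95e-05), the myosin-binding protein gene Mybph (-1.54 ± 0.17) and Bag3 (-1.41), Rgcc (-1.40), Mmp10 (-1.29), Clu (-1.19), Fgf1 (-1.08) and Hspa1l (-1.01). Of the heat shock list 12 of 18 were lower (14 adjusted over the list alone) and 1 was higher (1, list test adjusted p = 6.63e-12, but adjusted p = 0.0515 with an estimated correlation). Of the sarcomere strain list 7 of 18 were lower (13 adjusted over the list alone) and 1 was higher (3), with the annexin gene Anxa2 (1.15) higher (adjusted p = 5.73e-06). Cytokine genes gave 11 higher members of 23 (17 adjusted over the list alone, list test adjusted p = 9.57e-12, but adjusted p = 0.145 with an estimated correlation). Matrix genes gave 11 higher members of 34 (19 adjusted over the list alone, list test adjusted p = 1.92e-10, but adjusted p = 0.346 with an estimated correlation). Protease genes gave 8 higher members of 20 (13 adjusted over the list alone, list test adjusted p = 5.7e-08, but adjusted p = 0.208 with an estimated correlation). Interferon genes gave 4 higher members of 24 (11 adjusted over the list alone, list test adjusted p = 5.7e-08, but adjusted p = 0.354 with an estimated correlation). Without sample 436, with estimated-correlation adjusted p in brackets, 18 of 23 cytokine and chemokine genes (0.0369), 27 of 34 matrix genes (0.0393), 14 of 20 protease genes (0.0369) and 22 of 24 interferon genes (0.0369) were higher and 14 of 18 heat shock genes (0.0864, with 2 higher) and 13 of 18 sarcomere strain genes (0.0306, with 3 higher) lower. The rule then also named Cd53 (2.93) and Lilr4b (2.22) among the highest and Ces1d (-1.49) and Abcb4 (-1.21) among the lowest genes. The count was lower by over 1.5 times without any one of samples 417 (339), 445 (384), 418 (344), 446 (297), 421 (274), 463 (187), 460 (330), 464 (358), 449 (339), 467 (309), 450 (292), 468 (290), 425 (321), 453 (336), 440 (213) and 454 (229).

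**Figure D4:**
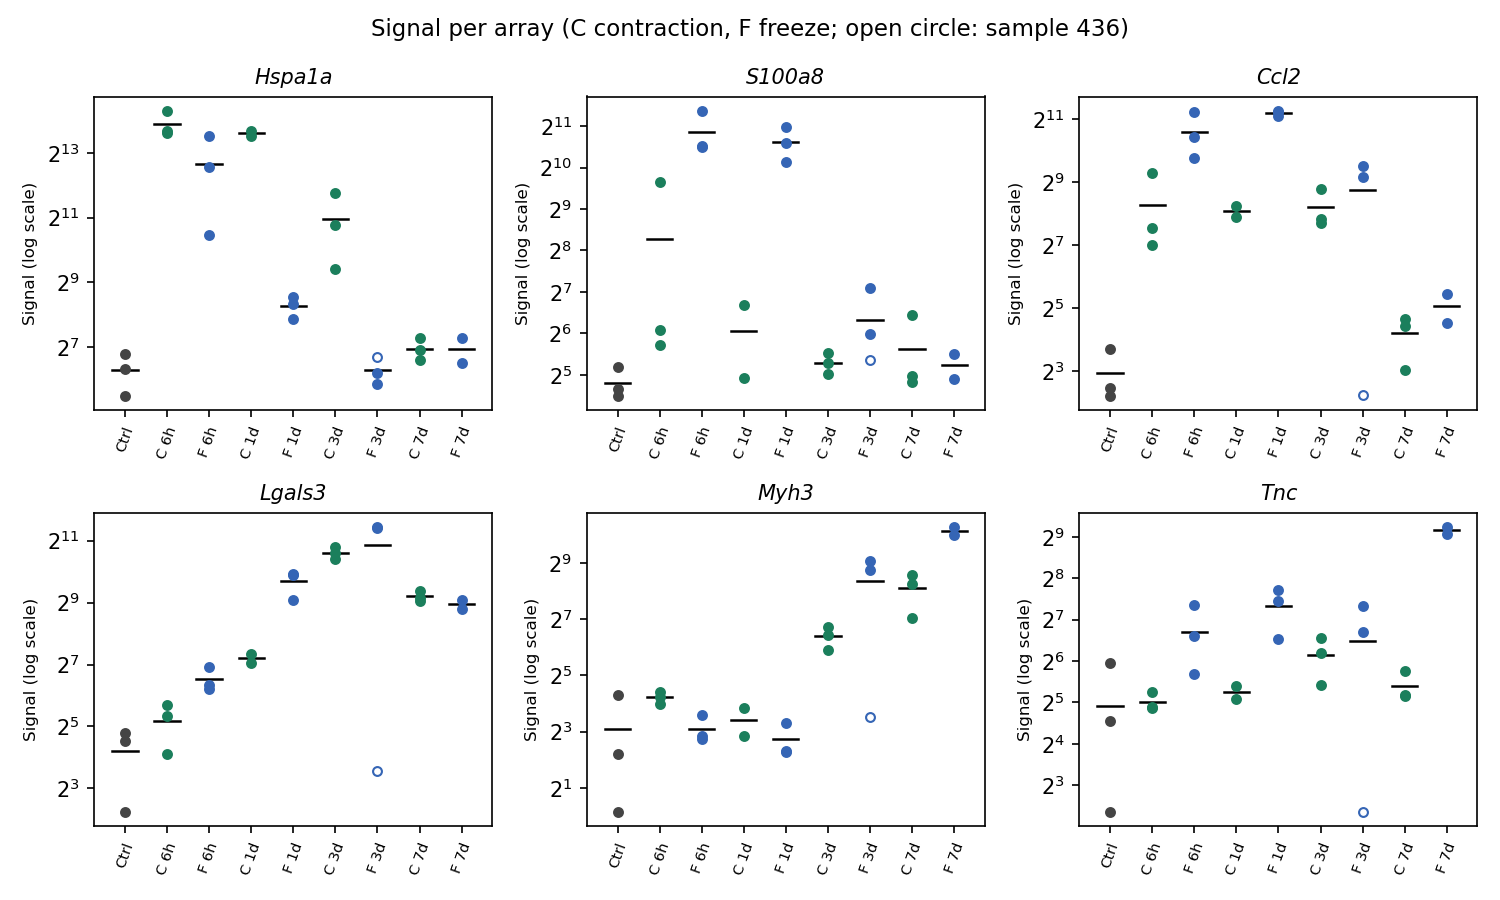
Signal per array (y axis, log scale) for 6 named genes in controls (grey), contraction (green) and freeze (blue) groups by time (x axis). Each point is 1 array, bars are arithmetic means of the signals, and the open circle is sample 436. Hspa1a is at 12384 after contraction and 312 after freeze at 1 day, and Tnc at 570 after freeze at 7 days.

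The difference between freeze and contraction itself changed over time in 56 probe sets, by limma's moderated F test of the injury by time interaction. The 3 with the smallest adjusted p, 0.000959 each, were Odc1, the first enzyme of polyamine synthesis, Csrp3 and Rcan1, a calcineurin regulator. Freeze minus contraction for Odc1 was 0.72 at 6 hours, 0.86 at 1 day, -1.5 at 3 days and -0.38 at 7 days, while for Csrp3 it was -1.34, -2.24, -2.61 and 1.25. The values at 3 days include sample 436, which lay among the controls. Without that sample the interaction was called in 423 probe sets. There were 34, 18, 32, 33 or 31 without sample 421, 463, 464, 440 or 454.

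Lists of markers of other cell types were tested too. None of the adipocyte, tendon and cartilage, smooth muscle, and erythroid and platelet lists passed the list test in any of the 13 comparisons, with all 25 arrays or without sample 436. Single members were called, among them Car3 (-1.60) and Thrsp (-1.09) lower after freeze at 3 days and Scd1 (1.99) and Acta2 (1.55) higher at 7 days. In the keratinocyte and epithelial list the difference at 3 days, with a median of -0.62, passed with 0 lower members of 8 (1 adjusted over the list alone, 4 at an unadjusted p under 0.05 by limma, list test adjusted p = 0.0221, but adjusted p = 0.237 with an estimated correlation), and without sample 436, with 1 lower member, it did not (adjusted p = 0.157). Mbp was lower against control at 1 and 3 days after both injuries and at 7 days after freeze, with values from -1.26 to -0.80. Only 1 of its 2 probe sets was called in each of these comparisons. Of the atrophy and autophagy genes 3 of 12 rose (4 adjusted over the list alone) at 6 hours after contraction (adjusted p = 1.57e-05) and 4 of 12 rose (4 adjusted over the list alone) after freeze (adjusted p = 0.00217), the metallothioneins Mt1 and Mt2 among them. Without sample 436 there were 4 rises and 1 fall of these after freeze. At 3 days Bnip3 (-1.78) and Mstn (-1.63) of that list fell after contraction and Bnip3 (-1.76) and Mstn (-1.5) after freeze.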

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

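The tests on sample 436 and on the heat shock genes were chosen after those results had been seen, while the other splits of the arrays were planned. No group had 4 or more arrays, so no test for a single outlying array within a group was made. Sample 436 stood apart by its array weight, 0.0768 against 0.428 to 2.28 for the others.

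The difference between the injuries changed over time in 56 probe sets. For Odc1, Csrp3 and Rcan1 the interaction had an adjusted p of 0.000959 each by limma. Freeze minus contraction for Odc1 at the 4 times in order was 0.72, 0.86, -1.5 and -0.38, for Csrp3 -1.34, -2.24, -2.61 and 1.25, and for Rcan1 0.18, -2.22, -1.58 and 0.14. The values at 3 days include sample 436. Genes with their extreme at 1 day were Ccn1, a matricellular protein gene, at -2.75 (adjusted p = 0.00366), Mmp10 at -3.87 (0.00369), Gadd45g at -2.58 (0.00767), Arg1 at 4.27 (0.00761) and the leukotriene receptor gene Ltb4r1 at 2.05 (0.00478). Dpt, dermatopontin, and Dlk1 differed at 7 days, by 2.26 and 2.55, with values between -0.03 and 0.25 and between -0.18 and 0.54 at the earlier times (adjusted p = 0.00369 and 0.00478). The count was 34, 18, 32, 33 or 31 without sample 421, 463, 464, 440 or 454, and 423 without sample 436.

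Sample 436, labelled freeze at 3 days, lay among the controls. A swap with another array of the series would need a partner, and 0 arrays outside the group were nearer to samples 450 and 468 than to their own group. Poor quality as the whole cause is argued against by its lowest correlation with a control, 0.935, above the lowest between controls, 0.921, and by a Gapdh 3'/5' ratio of 0.995, within the range of the other arrays. Its actin 3'/5' ratio, 0.741, was above the 3 controls at 0.560 to 0.595, so RNA of lower integrity than theirs stays open as a part of its profile. A freeze response of reduced size is argued against by the slope of its deviations from the controls on those of 450 and 468. The slope was taken over 1075 probe sets called in the same direction after freeze at 1 and 7 days. These calls came from a separate fit that left out all freeze arrays at 3 days. The slope was -0.0282, within the -0.0618 to 0.0670 of the controls themselves, where the injured arrays of other groups gave 0.101 to 0.713. RNA of an uninjured muscle is a candidate explanation that the same slope fits, though the actin ratio was above that of the uninjured muscles, and whether this came about by a wrong label, a sample from outside the series or an injury without response stays open.

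Heat shock genes were lower after freeze than after contraction at 1 day, with a list median of -1.78 (SD 1.85 over 18 genes). A lower share of fibre RNA after freeze is argued against as the whole cause, since the median lay -1.42 from that of the fast fibre list, -0.37 (SD 0.47 over 23 genes). Lower RNA integrity after freeze stays open. The lowest actin 3'/5' ratio after freeze, 1.01, was above both contraction arrays, 0.617 and 0.641, but Gapdh ratios of 0.825 to 1.04 overlapped 0.861 to 0.942. A difference in the injuries themselves also stays open and may account for it, untested beyond these values.

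With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 178 calls against at most 1 in another split for contraction at 6 hours, and 784 and 51 against at most 0 for contraction at 3 and 7 days. Freeze gave 461 at 6 hours and 1351 at 1 day, against at most 0. In each of these and for freeze minus contraction at 6 hours, 29 calls against at most 5, 1 of the 10 splits gave as many as the real one. For freeze at 3 days 4 of 10 splits gave at least the real 1698, up to 2425, and the other 3 of them placed sample 436 with controls. For freeze minus contraction at 3 days 3 of 10 gave at least the real 37, up to 2122, and the other 2 moved sample 436 to the contraction group. These many calls point to a structure of the samples set by that array. For the mean difference over times only the real split of 100, itself included, gave 581, with at most 49 in another. A count this large was thus rare among random splits. Splits that mix the injuries widen the spread, which lowers their counts, so they do not bound how much of the 581 is chance. Leaving out single arrays lowered the real count to as few as 187.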

How the results depend on the processing

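Leaving out sample 436 for list tests, overlaps and the naming rule was chosen after the data were seen, and the other alternatives were planned. Counts below are probe sets called, and the cause was not tested unless named.

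Quantile normalization, the filter at the 60th percentile, no trend, robust eBayes and 1 probe set per gene kept all counts within 1.5 times. With a pseudocount of 1 unit, freeze minus contraction gave 12 at 6 hours and 14 at 7 days, with a pseudocount of 2 times the 20th percentile 68 at 7 days, with a floor 18 at 6 hours, with median centring 23 at 7 days, and with no filter 17 at 6 hours. Median centring changed the split of the mean difference from 386 higher and 195 lower to 315 and 245. With adjacent sample numbers as a random block the counts were 17 at 6 hours and 22 at 7 days. Deviations of such pairs correlated at -0.36 to 0.15 and the consensus correlation was -0.0937, so the numbers share no visible pairing. The labels share no replicate number and name no pairs, so adjacent numbers were used only as a random block.

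With only the groups compared in the fit, the spread comes from these groups alone, so sample 436 bears only on comparisons with freeze at 3 days. Then contraction at 3 days gave 1215, freeze at 7 days 1079, and freeze minus contraction 1 at 6 hours, 924 at 1 day and 598 at 7 days. Freeze at 3 days gave 0, with 1328 at an unadjusted p under 0.05 by limma, freeze minus contraction at 3 days 0, with 351, and the overlap at 3 days 0. Array weights, which gave sample 436 a weight of 0.0768, raised contraction to 276, 381, 1885 and 159 over the 4 times, freeze to 929, 2399, 4567 and 2211, freeze minus contraction to 295, 1151, 2567 and 1398, its mean to 3561, the interaction to 732, any change to 5818 and the overlaps to 191, 268, 1691 and 128. Requiring a 2-fold change lowered freeze at 1 day to 872 and the mean difference to 150. An adjusted p under 0.01 gave 109, 102, 167 and 12 for contraction, 244, 492, 75 and 96 for freeze, 2, 50, 13 and 8 for freeze minus contraction, 122 for its mean, 22 for the interaction, 1032 for any change and 76, 50, 30 and 10 for the overlaps. The F tests have no value under the 2-fold rule, nor any change under the fit of compared groups.

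Leaving out each array gave these ranges, whose upper ends are those without sample 436. Contraction gave 128 to 319, 65 to 412, 227 to 2163 and 13 to 288, and freeze 273 to 1083, 684 to 2544, 7 to 4029 and 42 to 1855. Freeze minus contraction gave 0 to 224, 22 to 964, 14 to 1611 and 7 to 691, its mean 187 to 2939, the interaction 18 to 423 and any change 1937 to 4686. The overlaps ranged from 88 to 237, 43 to 310, 5 to 1886 and 12 to 232. The 0 at 6 hours, without sample 446, came with 602 at an unadjusted p under 0.05 by limma.

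Of 2125 gene and comparison values, 484 were called, and none of these 484 reversed under any alternative. Reversals were counted among called values only. Some of these genes were named because every array of one group lay beyond every array of the other. A stable sign was thus partly built in. Without sample 436, 476 more were called and 0 lost, while leaving out a control lost 110 to 142. Of 416 list results 173 were called, and turns of sign were counted among these only. The sign turned for the myogenic list of freeze minus contraction at 3 days, from -0.22 to 0.0391 with array weights (adjusted p = 0.897 by camera). Leaving out arrays gave that list -0.353 to 0.193, the latter without sample 436 (adjusted p = 0.76). It also turned for oxidative phosphorylation, to 0.0260 and 0.0763 without sample 450 or 468 (adjusted p = 0.488 and 0.396), over a range of -0.901 to 0.0763. The signal is limited at its lower end, since the pseudocount of 13 units is the 20th percentile of all values, so changes of dim genes are understated.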

Other observations

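The test of clock genes was fixed after Dbp had been seen and before the other clock genes were looked at, while the genes of the first paragraph were picked after their values were seen and are given without a test beyond the calls.

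Keratin genes of simple epithelia, which regenerating tissue can also express, rose after both injuries. Krt8 and Krt18 had values of 2.08 and 2.47 after contraction at 3 days and 3.11 and 3.36 after freeze at 7 days, all called by limma. Among cytochrome oxidase subunits the muscle isoforms Cox6a2, Cox7a1 and Cox8b fell after freeze at 3 days (-1.71, -2.12 and -1.82), while Cox6a1, the isoform of other tissues, rose (1.38). Without sample 436 the values of these 4 genes were -2.72, -3.40, -2.92 and 1.92. Cox7a2, the counterpart of Cox7a1, had a value of -0.72 that was not called, but was called at -1.22 without the sample. At 7 days the slow troponin genes Tnnt1 and Tnni1 rose after contraction (3.61 and 3.51) and after freeze (4.09 and 4.68), whereas the slow light chain gene Myl3 had values of -2.05 and -1.75. Igf2 rose after both injuries at 7 days (2.64 and 3.25).

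Dbp, a clock output gene, was lower at 6 hours after contraction (-1.97) and freeze (-3.36). Collection at another time of day than the controls may account for this, as a hypothesis, and the sources used here give no time of day. It predicts falls in the genes that cycle with Dbp and rises in those that cycle against it. After freeze the 5 tested genes in phase had a median of -0.43, with Tef at -1.48 (adjusted p = 0.00431) and Per2 at 0.50, and the 4 in antiphase had a median of 0.61, with Nfil3 at 2.63 and Clock at -0.14. After contraction the medians were -0.43 and 0.92, with Arntl at 1.29 (adjusted p = 0.0126) and Nfil3 at 3.26, while Per2 at 0.89 and Nr1d1 at 0.70 were not called. The bounds fixed for freeze were an in-phase median below -0.5, with the antiphase median at least 0.5 above it, for the time of day, and an in-phase median above -0.3 against it. The in-phase value lies between them, so an effect of the time of day and an effect of injury cannot be told apart.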
